A study of Oryza sativa with 12 samples.

How the data were processed

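RNA sequencing libraries of rice seedlings were compared, 12 in all, in 4 groups of 3 (cultivar IR64 or N22, in water or in polyethylene glycol). Groups and replicate numbers were taken from the submitters' sample labels. The deposited values are FPKM (fragment numbers scaled by transcript length and by library size), estimated by the authors with Cufflinks 2.2.1 after alignment with TopHat 2.1.1, per the series design text and the submitters' processing notes. Per the design text, reads were filtered with NGSQC Toolkit 2.3.3 and aligned to the RGAP 7.0 rice genome with bowtie 2.3.3.0. It also names edgeR for the submitters' own comparison, which is not used here, and missForest for filling a value missing in 1 replicate. It does not say whether the deposited values hold filled ones. Loci missing from a single replicate do occur in them.

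Each library lists loci with an FPKM above 0. Over all libraries there were 39718 rows, 25730 of them in every library. Of the rows, 2467 carried no locus name and are given by their assembly identifier, 1331 named more than 1 locus, and 100 bore another name. Rows of the same name were summed (1233 shared a name), leaving 39093 loci. A locus missing from a library counted as 0, which can also be a failed estimate. Of the ratios of low values between libraries, 4.08% to 17.2% lay within 1% of the commonest ratio. The share that would arise with no common step was not computed, so whether there was one is not known. Read counts were not recovered, depth is unknown and no counting intervals are given. Values were not scaled further.

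Loci with an FPKM of at least 1 in 2 of 3 replicates of at least 1 group were tested, 24276 in number. Group means of log2(FPKM + 1) over all 12 libraries were fitted with limma 3.58.1 in R 4.3.3 with an intensity trend and two-sided moderated tests. Adjustment was by Benjamini-Hochberg over the loci tested in each of 5 contrasts, namely drought in each cultivar, their difference, and the cultivars in each condition. A gene was called at an adjusted p of at most 0.05 and an absolute log2 change of at least 1, thresholds that the design text gives. The files were read with the R package data.table (version 1.17.8) and with pandas 2.3.3 in Python 3.11.15, and plots drawn with matplotlib 3.10.9.

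The design, thresholds, gene lists, naming rule and most alternatives were fixed before the data were examined. The 18 lists cover LEA proteins and dehydrins, ABA synthesis and breakdown, clade A PP2C phosphatases, SnRK2 kinases, drought transcription factors, DREB1/CBF factors, proline and compatible sugars, PIP and TIP aquaporins, photosynthesis, root markers, DNA replication and cell division, expansins, heat shock, antioxidant enzymes, jasmonate, gibberellin and the circadian clock. Of 198 pairs of symbol and locus, 153 symbols were found in a gene list of another rice assembly (ASM3414082v1), whose chromosome matched for 150. The 3 that contradicted it (RAB25, NAC10 and AP37) were dropped and 1 locus was in no library, leaving 194. Of these, 11 shared a row with other loci. PIP2;8, HSP16.9B, HSP16.9C, HSP26.7, NRT2.1 and NRT2.2 lay below the filter. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 18 lists.

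In each drought contrast the naming rule took the loci with the largest rise and fall whose 3 drought and 3 control values did not overlap. It added from each list the 2 called members with the largest change, or the most abundant member where none was called. For the difference of the responses it took the called loci of smallest adjusted p, and for the cultivar contrasts those of largest change, with called list members (at most 6). No table pairs the remaining identifiers with products, so 2 identifiers each way were printed instead of the 4 or 5 the rule foresaw.

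Same-numbered libraries of the groups compared deviated from their group means together (12 of 12 correlations above 0.1, from 0.118 to 0.595). Those of groups that differ in both cultivar and treatment gave 5 of 6 above 0.1, from 0.057 to 0.185. The numbers, which come from the labels, were therefore taken to pair the samples. A fit with a replicate block was run as an alternative and called 2132 loci in IR64. Other alternatives were a pseudocount of 0.1, other filters, rows tested singly, quantile and median-of-ratios scaling, no trend, array weights, the adjusted p alone, only the 6 libraries compared, and leaving out each library. Added after the data were seen were fits without the third drought library of each cultivar, with numbers 1 and 2 alone, with both block and quantile scaling, and with a block in the 6 libraries compared. The interaction count was also compared with sets in which residuals of a model with cultivar and treatment effects alone were exchanged within replicate numbers.

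On simulated data of 24276 loci for the N22 drought contrast, 92%, 92%, 100% and 100% of 50 changes each of 3, 4, 8 and 16 fold were recovered with 3 false calls. For the difference of the responses the shares were 72%, 86%, 96% and 98% with 7 false calls. These shares and false calls describe the simulated data alone. Whether they hold for the real loci, those of low FPKM among them, was not tested. The real libraries also deviated together by replicate number, and the third drought libraries responded less. No coordinates are given, because no genome of the build used was at hand.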

Results

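Rice (Oryza sativa) seedlings of 2 cultivars were compared by RNA sequencing. IR64 is described by the submitters as sensitive to drought and N22 as tolerant. Seedlings 21 days old stood for 6 h in water (control) or in 20% polyethylene glycol 6000, a polymer that lowers the water potential around the roots (called drought here). Each of the 4 combinations of cultivar and treatment had 3 libraries, 12 in all. The labels give no organ, so the values are those of seedlings. Each library listed 30625 to 32107 rows with an FPKM above 0, and its FPKM values summed to between 684525 and 761822. Median FPKM of the listed rows lay between 4.44 and 5.18. The depth in reads is unknown, because FPKM values carry no counts. Values are FPKM as mean ± SD (n = 3), and changes are on the log2(FPKM + 1) scale with their standard error (SE), which understates the change of low genes. A gene rose or fell where limma's adjusted p was at most 0.05 and its change at least 1 on that scale.

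The libraries separated by cultivar and by treatment. On log2(FPKM + 1) values of the 24276 loci tested, the first principal component held 51.8% of the variance and parted N22 (scores 54.01 to 83.07) from IR64 (-74.62 to -55.79). The second component held 34.6% and parted drought from control within each cultivar. Control libraries scored 36.26 to 66.17 on it. The drought libraries numbered 1 and 2 scored -57.18 and -74.95 in IR64 and -62.00 and -77.48 in N22, whereas the third scored -30.67 in IR64 and -6.62 in N22, nearer to the controls. Pearson's r between replicates was 0.984 to 0.989 in the control groups, 0.956 to 0.978 in IR64 under drought and 0.955 to 0.986 in N22 under drought. No pair of libraries held identical values.

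**Figure D1:**
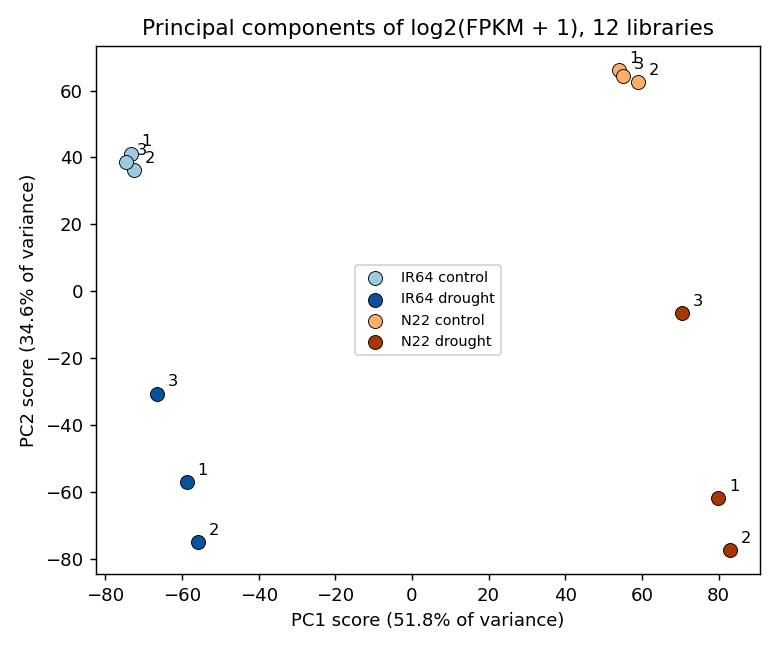
Scores of the 12 libraries on the first principal component (x axis, 51.8% of variance) and the second (y axis, 34.6% of variance) of log2(FPKM + 1); colours mark the 4 groups and numbers the replicates. The drought libraries numbered 3 lie at -30.67 (IR64) and -6.62 (N22) on the y axis, between the other drought libraries and the controls.

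In IR64 under drought, 8 of 8 late embryogenesis abundant genes and 8 of 9 phosphatases of abscisic acid (ABA) signalling rose, while 6 of 10 expansins and 8 of 12 genes of DNA replication and cell division fell. All 8 late embryogenesis abundant (LEA) proteins and dehydrins tested, which protect cells during water loss, rose. RAB16A (LOC_Os11g26790) went from 1.33 ± 0.863 to 452 ± 279 FPKM, a log2 change of 7.45 (SE 0.65, adjusted p = 0.000178). OsLEA3 (LOC_Os05g46480) went from 5.36 ± 1.37 to 536 ± 333 FPKM, a log2 change of 6.18 (SE 0.60). Both were higher in 3 of 3 drought libraries than in any control.

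Of 9 clade A PP2C phosphatases in IR64, which restrain ABA signalling, 8 rose, PP2C51 by 3.48 (SE 0.44) and PP2C68 by 2.93 (SE 0.58). Of 8 genes of ABA synthesis and breakdown, 4 rose. These were NCED4, an enzyme of ABA synthesis, by 3.41 (SE 0.63), ABA8ox2, an enzyme of ABA breakdown, by 2.42 (SE 0.20), ZEP1 by 2.01 and NCED3 by 1.36. Among 10 SnRK2 kinases, SAPK1 rose by 1.69 (SE 0.29) and the other 9 did not pass. Of 16 drought transcription factors 5 rose (6 adjusted over the list alone), ZFP182 by 3.41 (SE 0.58) and NAC6 by 1.86 (SE 0.29), with bZIP12, bZIP23 and bZIP72. None of 5 rows of DREB1/CBF factors passed. The row shared by DREB1A and DREB1B stood at 131 ± 24.6 FPKM in control and 141 ± 158 under drought, and without the third drought library it was called lower (log2 change -1.37, adjusted p = 0.0264), whereas without the second the change was 0.13 and not called. At an unadjusted p below 0.05 stood 1 of the 5.

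Of 10 expansins in IR64, which loosen cell walls, 6 fell, EXPA2 by -2.37 (SE 0.44) and EXPB11 by -2.33 (SE 0.43). Of 12 genes of DNA replication and cell division 8 fell, among them the replication clamp PCNA by -1.36 (SE 0.39), the cyclin CYCB2.2 from 12.6 ± 0.293 to 5.05 ± 1.48 FPKM, and 5 MCM helicase subunits. The PCNA call was lost without any 1 of the controls or without the first or the second drought library (adjusted p = 0.0508 to 0.0900), and that of CYCB2.2 without any 1 of the controls or the second drought library (0.0536 to 0.0800) and with array weights (log2 change -0.96). Among 19 photosynthesis genes 5 fell and 3 rose, and the list was not called (adjusted p = 0.623). RBCS2, a small subunit of Rubisco, went from 6728 ± 1107 to 1713 ± 429 FPKM (log2 change -1.99, SE 0.41, adjusted p = 0.00639), and RBCS3, RBCS4, the Rubisco activase RCA and LHCB4 fell too. The RBCS2 call was lost with no filter on low values (adjusted p = 0.0845). CAB1R, a chlorophyll-binding protein, rose by 2.07 (SE 0.31), with LHCA3 and LHCB2. The unnamed loci LOC_Os12g06660 and LOC_Os07g48050 had the largest falls among loci with separate groups, by -3.24 (SE 0.51) and -3.09 (SE 0.28).

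Other lists held few calls in IR64. Of 10 heat shock genes tested, HSP17.9A rose by 2.86 (SE 0.48) and the chaperone HSP101 by 1.19 (SE 0.25). Of 9 genes of proline and compatible sugars 3 rose, namely the galactinol synthase GolS2 by 2.34 (SE 0.51) and the proline enzymes P5CS2 by 1.34 (SE 0.27) and P5CS1 by 1.16. Of 10 clock genes 3 rose, PRR95 by 1.41 (SE 0.21), GI by 1.12 (SE 0.26) and PRR59 by 1.02. Of 5 gibberellin genes GA2ox3, which inactivates the hormone, rose by 1.35 (SE 0.29) and the synthesis gene SD1 by 1.14 (SE 0.28). The call of GA2ox3 was lost without the third drought library (log2 change 0.97), that of SD1 without the third control (0.88) or the second drought library (0.96) or with array weights (0.84), and that of GI without the second control (0.89). With numbers 1 and 2 alone SD1 (adjusted p = 0.0935) and GI (0.0519) were not called. Of 14 antioxidant enzymes the catalase CATB rose by 1.11 (SE 0.18, or 1.00 and not called without the second drought library). Of 5 tonoplast water channels TIP1;2 rose by 1.59 (SE 0.47), a call lost without the first or the second library of either treatment (adjusted p = 0.0614 to 0.0942), with no filter (0.0552) and with only the 6 libraries compared (0.0576, or 0.0865 with a block). No plasma membrane water channel (10 tested), root marker (10) or jasmonate gene (17) passed, with 4, 1 and 4 of them at an unadjusted p below 0.05. The most abundant of each were PIP1;2 at 684 ± 95.7 and 1011 ± 188 FPKM, the silicon transporter Lsi1 at 304 ± 24.5 and 244 ± 23.6, and JAZ7 at 404 ± 95.3 and 259 ± 84.5.

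Over loci changed by at least 1 in the other 2 libraries, the changes of the third drought library had a slope of 0.641 on theirs. For the first and the second it was 0.943 and 1.083, on pairs that held the third. The 3 slopes thus rest on different loci and pairs. Over all loci tested, 2031 passed in IR64, 1055 higher and 976 lower under drought. In camera with a preset correlation of 0.01, 9 of the 18 lists were called. The LEA (adjusted p = 1.73e-07), PP2C (3.62e-05), transcription factor (4.73e-05), clock (0.00110), heat shock (0.00616), ABA (0.00646) and SnRK2 (0.0359) lists were called upward, and the expansin (4.73e-05) and DNA replication (0.000170) lists downward. None of the 9 was called with an estimated correlation (adjusted p = 0.327 to 0.353 with an estimated correlation). In fry, which asks whether the genes of a list move one way, all 9 were called (0.000936 to 0.0252), with the proline (0.00347) and TIP (0.0151) lists. The SnRK2 call in camera was also lost with a replicate block (adjusted p = 0.0728), quantile scaling (0.0809), a block and quantile scaling together (0.155), an FPKM minimum of 5 (0.0663), only the 6 libraries compared (0.0712, or 0.122 with a block), without the second control (0.0794) and without the first drought library (0.0562). Among lists not called, the median and the test differed in sign for the DREB1 (median -0.16, mean -0.04, tested upward) and PIP (0.04, mean -0.15, downward) lists, and the mean differed from both for the antioxidant list (-0.09, mean 0.02, downward). Counts adjusted over the list alone equalled those over all genes for every list except the transcription factors. The series design text speaks of biological replicates but nothing in the labels says that they came from separate cultures, so the p-values measure the spread between these libraries.

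**Figure D2:**
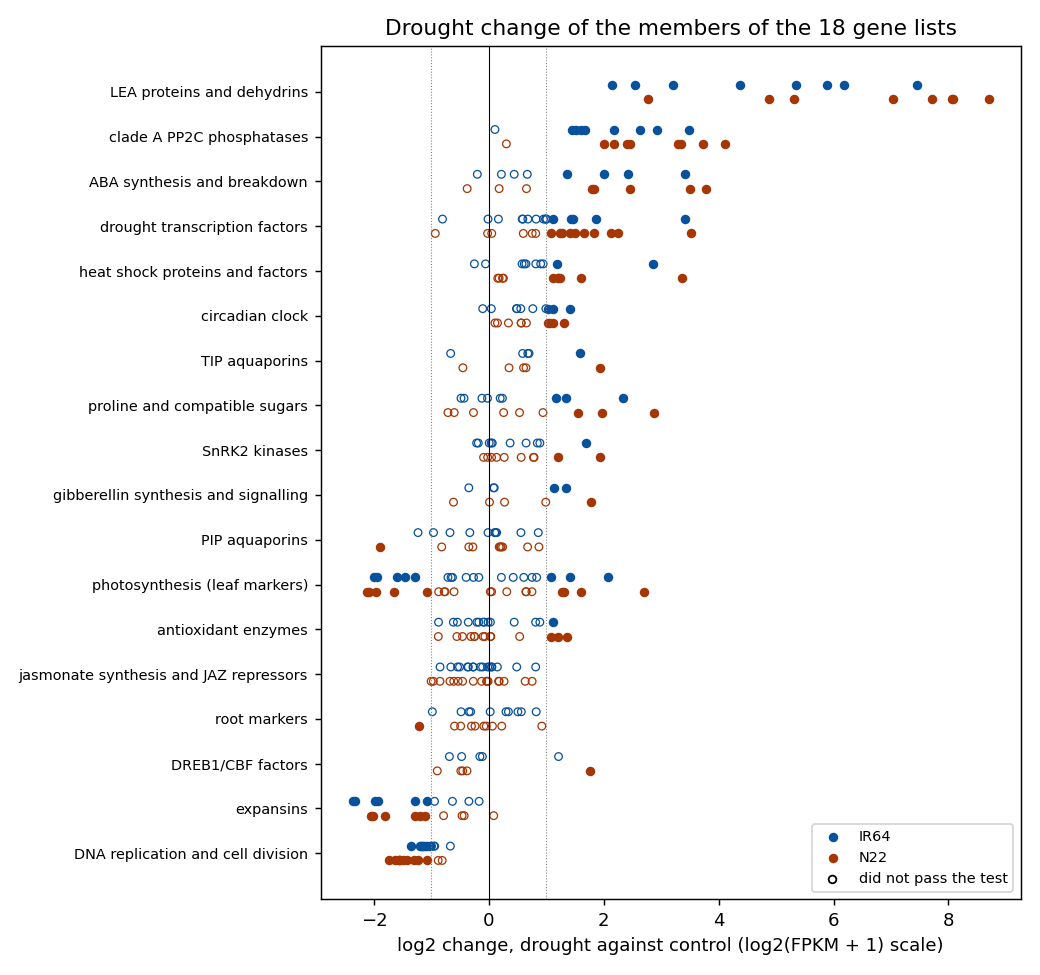
Change between drought and control (x axis, log2(FPKM + 1) scale) of each tested member of the 18 gene lists (y axis), blue for IR64 and brown for N22; filled points passed the test, open points did not, and dotted lines mark changes of -1 and 1. All 8 members of the LEA and dehydrin list lie above 1 in both cultivars.

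In N22 under drought, 8 of 8 LEA genes, 8 of 9 PP2C phosphatases and 10 of 16 drought transcription factors rose, while 10 of 12 replication and division genes and 6 of 10 expansins fell. All 8 LEA and dehydrin genes rose. RAB16A went from 4.41 ± 3.06 to 2270 ± 1279 FPKM, a log2 change of 8.70 (SE 0.65, adjusted p = 3.83e-05), and OsLEA3 from 6.64 ± 4.48 to 2006 ± 1018 FPKM, a change of 8.08 (SE 0.60). Among clade A PP2C phosphatases 8 of 9 rose, PP2C51 by 4.12 (SE 0.44) and PP2C68 by 3.72 (SE 0.58). ABA8ox2 rose by 3.50 (SE 0.20) from 6.99 ± 0.556 to 91.8 ± 26.5 FPKM and NCED4 by 3.77 (SE 0.63). With ZEP1, NCED3 and ABA8ox3 they made 5 of the 8 ABA genes.

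Of 16 drought transcription factors in N22 10 rose, ZFP182 by 3.52 (SE 0.58), NAC6 by 2.25 (SE 0.29) and, among others, SNAC1, DREB2A and bZIP46. The SnRK2 kinases SAPK1 and SAPK6 rose by 1.93 (SE 0.29) and 1.21 (SE 0.21), out of 10. DREB1C rose by 1.76 (SE 0.51), the only call among 5 DREB1/CBF rows, and it was lost without the first or the third control or the first or the second drought library (adjusted p = 0.0561 to 0.0763). Of 10 heat shock genes 5 rose, HSP17.9A by 3.36 (SE 0.48) and HSP101 by 1.60 (SE 0.25), with HSFA2a, HSFA2c and HSP18.2. Of 14 antioxidant enzymes 3 rose, CATB by 1.35 (SE 0.18) and the superoxide dismutases SODCC2, from 231 ± 10.8 to 539 ± 107 FPKM, and SODA1. GolS2 rose by 2.87 (SE 0.51), P5CS2 by 1.97 (SE 0.27) and P5CS1 by 1.55, as 3 of 9. Of 10 clock genes PRR95 rose from 8.86 ± 0.351 to 23.7 ± 5.72 FPKM, GI by 1.12 (SE 0.26, or 0.91 and not called without the second control), PRR73 by 1.07 and PRR59 by 1.02. GA2ox3 rose by 1.77 (SE 0.29), as 1 of 5 gibberellin genes.

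Of 12 replication and division genes in N22 10 fell, PCNA by -1.74 (SE 0.39) and MCM4 by -1.64 (SE 0.38). Of 10 expansins 6 fell, EXPB3 by -2.05 (SE 0.33) and EXPA2 by -2.02 (SE 0.44). RBCS2 went from 7232 ± 682 to 1917 ± 1250 FPKM (log2 change -2.12, SE 0.41, adjusted p = 0.00331, or 0.0560 with no filter on low values). RBCS3, RBCS4, RCA and LHCB4 made it 5 of 19 photosynthesis genes that fell, against 4 that rose, CAB1R by 2.70 (SE 0.31), LHCA3, LHCB2 and CAB2R, and the list was not called (adjusted p = 0.879). The water channels PIP2;7 and TIP1;2 went opposite ways, by -1.89 (SE 0.45) as 1 of 10 and by 1.94 (SE 0.47) as 1 of 5. RCc3, a root gene, fell by -1.22 (SE 0.33), the only one of 10 root markers, and its call was lost without the first control or the first or the second drought library (adjusted p = 0.0582 to 0.0626). None of 17 jasmonate genes passed, with 5 at an unadjusted p below 0.05. JAZ7 stood at 412 ± 19.9 and 238 ± 92.8 FPKM, and was called lower without the third drought library (log2 change -1.15). The unnamed loci LOC_Os04g11970 and LOC_Os02g44320 fell by -3.28 (SE 0.62) and -3.12 (SE 0.75).

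Over loci changed by at least 1 in the other 2 libraries, the changes of the third drought library had a slope of 0.527 on theirs. For the first and the second it was 1.104 and 1.266, on pairs that held the third. Here too the 3 slopes rest on different loci and pairs. Over all loci, 2845 passed in N22, 1591 higher and 1254 lower. In camera the LEA (adjusted p = 2.33e-08), PP2C (3.67e-06), transcription factor (1.93e-05), clock (0.00178), ABA (0.00335), heat shock (0.00335) and SnRK2 (0.00886) lists were called upward and the DNA replication (4.68e-05) and expansin (0.00112) lists downward. All 9 calls were lost with an estimated correlation (adjusted p = 0.285 to 0.347 with an estimated correlation), and that of SnRK2 also with a replicate block and quantile scaling together (0.0601). In fry all 9 were called (6.88e-05 to 0.00839), with the proline (0.000237), TIP (0.0207) and gibberellin (0.0392) lists. Counts adjusted over the list alone equalled those over all genes. Median and test differed in sign for the photosynthesis list (median 0.02, mean -0.14, downward) and the antioxidant list (-0.09, mean 0.10, upward), and the mean (-0.10) for the PIP list (0.19, upward), none of them called. The RBCS, CAB and RAB16 genes belong to families of similar sequence, between which reads can be split wrongly.

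**Figure D3:**
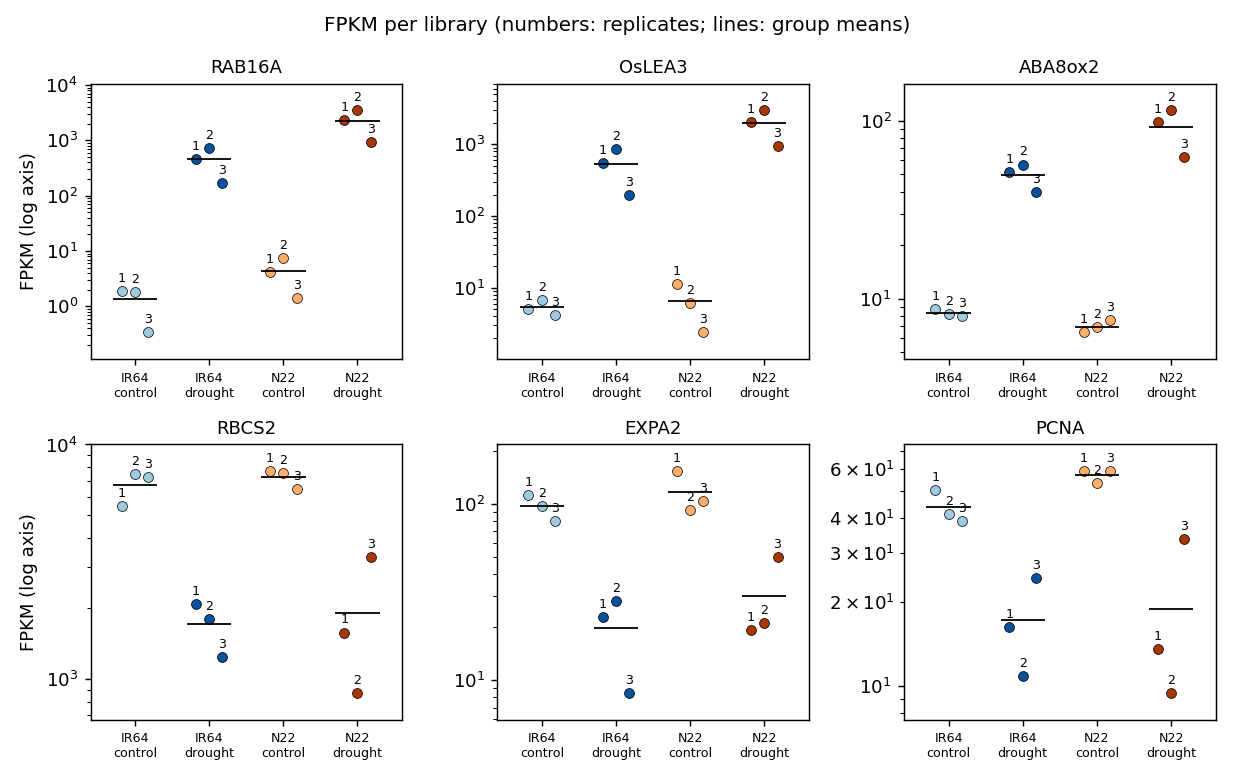
FPKM (y axes, log scale) of 6 genes in each of the 12 libraries by group (x axes); points are libraries with their replicate number, lines are group means. RAB16A averages 452 FPKM in IR64 and 2270 in N22 under drought against 1.33 and 4.41 in control.

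The responses of both cultivars overlapped widely. Of the loci that rose, 871 did so in both cultivars, 82.6% of the IR64 list and 54.7% of the N22 list, where independent lists would share 69.1. Of those that fell, 761 did so in both, against 50.4. Only 2 loci were called in opposite directions. Across the 24276 loci, which are not independent replicates, the changes in IR64 and N22 correlated with Pearson's r = 0.875 and Spearman's rho = 0.859. The comparisons share no library but are not fully independent, since they come from a fit with a shared spread per locus. Same-numbered drought libraries of the cultivars also deviated from their group means together (r = 0.36, 0.53 and 0.595). A further 397 loci passed in IR64 alone and 1211 in N22 alone. For only 26 and 26 of these did the test of the difference itself pass.

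The difference between the drought responses, N22 minus IR64, asks which genes respond unequally in the tolerant and the sensitive cultivar. No member of any of the 18 lists passed limma's test over all genes, and 7 of 187 list rows stood at an unadjusted p below 0.05. Within the LEA list the difference was 2.76 for OsEM1 (SE 0.82, adjusted p = 0.313), 2.71 for RAB16D (SE 0.73, 0.246) and 2.66 for RAB16C (SE 0.68, 0.219). OsEM1 was absent from all control files and counted as 0 there. Adjusted over the list alone, 3 of 8 LEA genes and 2 of 8 ABA genes passed. In camera the LEA list (median difference 1.86, adjusted p = 2.27e-06) and the PP2C list (median 0.72, adjusted p = 0.00668) were called higher in N22. Both calls were lost with an estimated correlation (adjusted p = 0.824 and 0.880 with an estimated correlation) and in fry (0.591 and 0.809). The PP2C call was also lost without the third IR64 drought library (0.252) and without the first (0.0638) or the second (0.124) N22 drought library.

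Over all loci, 60 passed, 46 with a positive and 14 with a negative difference (N22 minus IR64). The absolute change was larger in N22 at 31 of them and in IR64 at 29. XLOC_057537 was not listed in 9 libraries (counted as 0) and stood at 135, 89.2 and 57.0 FPKM in N22 under drought. LOC_Os01g06570 was not listed in any IR64 library and had a mean of 2.91 FPKM in N22 controls and values of 75.7, 46.2 and 42.4 under drought. XLOC_030054 was listed only in IR64 under drought (8.47 ± 1.75 FPKM), and XLOC_028673 went from 1.51 ± 0.646 to 17.8 ± 6.39 FPKM in IR64 with means of 0.00373 and 0.0121 in N22. These 4 are the IDs the naming rule leaves, and limma's adjusted p lay between 2.51e-05 and 0.00722. The count moved with single libraries, to 320 without the third N22 drought library, 93 without the third IR64 drought library, 23 without the third IR64 control, and 26, 29 and 29 without each N22 control. Without the third drought library of each cultivar it was 357, as an alternative chosen after the data were seen. The count was 924 with array weights, and 15 with only loci above 0 in all 12 libraries, where fewer loci were tested.

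N22 and IR64 differed at many loci in control conditions, but at few members of the gene lists. SD1 stood at 1.02 ± 0.575 FPKM in IR64 and 3.51 ± 0.897 in N22, a log2 difference of 1.19 (SE 0.28, or 0.93 and not called without the third IR64 control, and not called with numbers 1 and 2 alone, adjusted p = 0.0978). The kinase SAPK5 was lower in N22, at 96.2 ± 7.72 against 42.7 ± 3.71 FPKM, a difference of -1.15 (SE 0.11, adjusted p = 1.03e-05). No other list member passed, none of the 18 lists was called in camera (adjusted p = 0.958 for each, with 0 at an unadjusted p below 0.05), and no LEA gene passed, with 0 at an unadjusted p below 0.05. The widest differences were in loci not listed in one cultivar and counted as 0 there. LOC_Os01g03310 and XLOC_057524 stood at 5733 ± 1266 and 2078 ± 524 FPKM in N22 and were absent from all IR64 libraries. LOC_Os04g30290 and XLOC_010344 stood at 795 ± 212 and 979 ± 762 FPKM in IR64 and were absent from all N22 libraries. Over all loci 2407 passed, 1232 higher and 1175 lower in N22.

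Under drought the cultivars also differed in the LEA genes. Of the 8, 7 were higher in N22, RAB16D at 48.0 ± 24.9 against 384 ± 214 FPKM (difference 2.93, SE 0.51, adjusted p = 0.00149) and RAB16B at 94.6 ± 73.2 against 650 ± 371 FPKM (difference 2.92, SE 0.63). OsEM1 (2.76), RAB16A (2.36), RAB16C (2.28) and OsLEA3-2 (2.16) followed. With only the 6 drought libraries in the fit, RAB16A (adjusted p = 0.0658), RAB16B (0.0519), RAB16C (0.0542), OsEM1 (0.0537) and OsLEA3-2 (0.126) were not called. Neither that fit nor the main fit of all 12 libraries, which called them, takes account of the pairing of the samples by number. With a replicate block in the fit of 6 libraries all 5 were called (adjusted p = 0.000259 for RAB16A, 0.000420 for RAB16B, 0.000558 for RAB16C, 0.000268 for OsEM1 and 0.000169 for OsLEA3-2). With no block, the RAB16A call was also lost without the third IR64 drought library (0.0787) or the first (0.0725) or the second (0.0826) N22 drought library, and with a pseudocount of 0.1 (0.0561). That of OsLEA3-2 was lost without the first (0.0503) or the third (0.0754) IR64 drought library or the first (0.0711) or the second (0.0872) N22 drought library. The LEA list was called in camera (adjusted p = 0.00770), but not with an estimated correlation (adjusted p = 0.969 with an estimated correlation) nor in fry (0.0764). With a replicate block in the fit of 6 libraries the PP2C (0.000294) and ABA (0.0343) lists were also called in camera at the preset correlation, higher in N22, and PP2C with a block and quantile scaling (0.0469). In the main fit neither was called in camera (0.117 and 0.340), with an estimated correlation (0.969 each) or in fry (0.173 and 0.0764). An estimated correlation was not tried with a block. Named after their values were seen, OsLEA3 (1.99) was the seventh LEA gene, and the other list members higher in N22 were ABA8ox3, PP2C06, PP2C09, GolS1, HSP101 and SD1, and the ammonium transporters AMT1.2 and AMT1.3 were lower. Over all loci 2604 passed, 1412 higher and 1192 lower in N22. Of these, 998 were higher and 969 lower in both conditions, against 71.7 and 57.7 for independent lists. Both lists came from a fit with a shared spread per locus. XLOC_035570 and XLOC_010344, not listed in N22, stood at 1141 ± 1025 and 1367 ± 508 FPKM in IR64, and LOC_Os01g03310 and XLOC_057524, not listed in IR64, at 3487 ± 3007 and 1620 ± 728 FPKM in N22.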

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

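The tests of explanations in this part, except that of expression near the detection limit, and the splits and residual sets were chosen only after the result was seen.

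The results here are those in which the drought response differed between cultivars by the interaction test. Loci that passed numbered 60. In camera with a preset correlation the LEA list (adjusted p = 2.27e-06) and the PP2C list (0.00668) were called higher in N22. Both calls were lost with an estimated correlation (adjusted p = 0.824 and 0.880 with an estimated correlation) and in fry (0.591 and 0.809). The 4 loci named were XLOC_057537 (6.48), LOC_Os01g06570 (3.79), XLOC_030054 (-3.23) and XLOC_028673 (-2.86), on the log2(FPKM + 1) scale; the first 3 are not listed (counted as 0) in at least a whole group, so these are no fold changes. Of 100 splits of the treatment labels within cultivars, 1, the real one, called as many loci as the 60, and the highest other called 24. Exchanging these labels also breaks the drought effect, so the splits do not test the interaction alone. Residuals of a model with no interaction, with the cultivar and treatment effects kept, were therefore exchanged within replicate numbers. Of 100 such sets, 2 called as many as 60, the real one included, and the median of the others was 0. The highest other called 60, and whether its exchange rebuilt the real grouping was not checked. Residuals of control libraries were mixed with those of drought libraries, whose replicates correlated down to 0.955. The count itself was fragile: leaving out 1 library gave 23 (the third IR64 control) to 320 (the third N22 drought library).

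The median interaction of the LEA list was 1.86 toward N22, with no member called over all genes and the list's call lost with an estimated correlation (adjusted p = 0.824 with an estimated correlation) and in fry (0.591). The third drought libraries were weighed as a source; without them the median stayed at 1.72, which argues against them. A response scaled up over all genes in N22 stays open. Over the line of the 863 loci that rose in both cultivars the members' median excess was 0.377 (interval -0.351 to 0.996). Over that of all loci it was 0.752 (0.158 to 1.704). These intervals and those below came from resampling the 8 members, so they do not measure the spread between libraries. A general and a specific larger response cannot be told apart. In number 3 taken singly the LEA excess was 1.201 (0.948 to 1.554) and 2.725 (1.761 to 3.22) over these lines. There the major axis over all loci was 0.911, but the slope of loci that rose in both cultivars was 1.335. In numbers 1 and 2 the excess was 0.288 and 0.202 over the first line. Over the second it was 0.279 in each (-0.75 to 1.24 and -0.661 to 1.71). With 1 library per group, no conclusion is drawn from single numbers. A difference between the cultivars in the regulation of these genes may add to the larger rise in N22, and was not tested.

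The third drought library of each cultivar lay nearer to the controls. Scaling is argued against by a slope of 0.538 in N22 after quantile normalization. Control RNA mixed into a library like the mean of the first and the second would shrink rises and falls alike in FPKM. The share of change kept differed between falling and rising loci by 0.39 in IR64 and 0.165 in N22, which argues against such mixing. That share was not computed for the first or the second library, and mixing into a library unlike their mean stays open. A run or day effect on all libraries numbered 3 stays open, since the deviations of the third control and the third drought library correlated at 0.131 in N22 and 0.261 in IR64, as those of the other numbers also did. A weaker or shorter treatment shared by these libraries may also account for it; the labels give nothing to test this.

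Among the 24276 loci tested, 487 were absent from all IR64 libraries and 400 from all N22 libraries. Sequence that one cultivar lacks, or that does not map to the reference, may account for part of them: the 263 of the 487 with a single locus name formed 40 adjacent pairs along the chromosomes, against at most 10 in shuffled orders, and the 204 of the 400 with such a name formed 21 against at most 7. These were 12.45 and 10.64 times the shuffled mean. Other loci higher (628) or lower (652) in N22 controls formed 71 and 83 pairs, 3.88 and 4.22 times. Those called under drought stood at 1.53 to 2.15 times. At a like clustering per locus the ratio falls as a set grows, so it does not compare sets of unlike size. These other sets also exceeded all their shuffled orders, so adjacency does not set the absent loci apart. Of the 887 loci absent from either cultivar, 192 reached a mean of 10 FPKM in the other, or 21.6% (exact binomial interval 19.0% to 24.5%). Over 20% had been set as the bound against expression near the detection limit. The share passed that bound, but its interval reached below it. The filter had removed loci of low FPKM beforehand, which raises the share. It therefore cannot weigh this explanation for all loci absent from one cultivar. For the 192 loci the values argue against expression near the detection limit, and for the rest it stays open. A biological difference in expression was not tested.

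For the pairwise comparisons the 10 splits of 6 libraries are too few for a share under 0.05. The real and highest other counts were 2031 and 2 for drought in IR64, 2845 and 1 in N22, 2407 and 0 between cultivars in control, and 2604 and 355 under drought; in each, 1 split, the real one, called as many.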

How the results depend on the processing

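The tests without the third drought library of each cultivar, with numbers 1 and 2 alone, with block and quantile scaling together, and with a block in the 6 libraries compared were chosen only after the results were seen. Of the comparisons of named genes with an alternative, 2242 kept their direction and side of the threshold, 51 lost the call and 9 gained it; DREB1A in IR64, not called, turned from -0.48 to 0.13 without the second drought library (range -1.37 to 0.13 over left-out libraries). For called lists 590 kept the call and 36 lost it. Lists not called gained one in 38 of 2038 comparisons. Without the third drought libraries these were jasmonate in IR64 (downward, adjusted p = 0.0297), ABA (0.0300), transcription factors (0.00448) and, downward, DNA replication (0.000290) in the interaction, and PP2C between cultivars under drought (0.00292). All are camera calls at the preset correlation. An estimated correlation and fry were tried only with all libraries, where these lists stood at adjusted p = 0.824 to 0.991 and 0.173 to 0.889. Counts of called loci moved by over 1.5 times as follows. With the adjusted p alone, which drops the fold threshold, they were 7272 in IR64, 9475 in N22, 5872 shared, 4626 between cultivars in control and 5749 under drought. With an FPKM minimum of 5 the cultivar counts were 1370 and 1586, and with only loci above 0 in all 12 libraries 1160 and 1318, where fewer loci were tested. The interaction count of 60 became 15 with only loci above 0 in all libraries, 924 with array weights, 357 without the third drought libraries and 93 with numbers 1 and 2 alone; the cause was not tested. Leaving out 1 library gave 23 to 320 (23 without the third IR64 control, 26, 29 and 29 without each N22 control, 93 without the third IR64 and 320 without the third N22 drought library). Its share of positive differences, 76.7%, ranged from 59.1% to 91.3%. With a replicate block the counts were 2132, 2921, 53, 2464 and 2712 for IR64, N22, the interaction, control and drought. Of the reported calls the block kept 2030, 2843, 49, 2403 and 2603. Among named genes and lists it changed only the SnRK2 call in IR64 (adjusted p = 0.0728), and with quantile scaling added 0.155 in IR64 and 0.0601 in N22. A block in the 6 libraries compared lost the calls of SnRK2 (0.122) and TIP1;2 (0.0865) in IR64 and gained PP2C (0.000294) and ABA (0.0343) between cultivars under drought. With all 12 libraries, no block and an estimated correlation, camera gave PP2C and ABA an adjusted p of 0.969 each there. Depth is unknown and its limit could not be assessed.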

Other observations

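The tests of this part were chosen only after the result was seen.

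Some loci went from near silence to clear expression. Below 1 FPKM in all 6 controls and at 10 FPKM or more in all 6 drought libraries were 5 loci, RAB16D among them, and 0 loci did the reverse. Within the members called in both cultivars, the PP2C genes PP2C30 (2.18 in IR64, 3.29 in N22) and PP2C49 (2.63, 3.35) rose beside those named above. EXPA4 (-1.93, -1.81) and EXPB4 (-1.29 in each) fell in both. These genes were named after their values were seen.

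Among the 10 libraries without the third drought library of each cultivar, members called in the interaction were RAB16C (2.83, adjusted p = 0.00403), RAB16D (2.78, 0.000440), OsEM1 (2.71, 0.00106) and ABA8ox2 (1.19, 0.00446) by limma. With all 12 libraries none of them was called.

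Loci without an annotated name made up 6.2% of the loci tested, 22% of the calls between cultivars in control, 44.1% of the tested loci not listed in one cultivar, and 3.8% and 3.7% of the drought calls in IR64 and N22.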
